A study of Homo sapiens with 6 samples.

How the data were processed

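Transcript levels of SH-SY5Y cells were measured by RNA sequencing in 3 libraries from cells given DMSO and 3 from cells given SGC707, grouped by the treatment in the labels. Per the labels' protocols, total RNA was treated with DNase, mRNA was isolated and fragmented, and libraries made with an Illumina-type mRNA kit were sequenced on a NovaSeq instrument as paired reads. The deposited table holds whole-number read counts per gene symbol that the authors made and did not scale between libraries. HISAT2 and StringTie are named as tools and GRCh38 as the genome build per the submitters' processing notes. Their versions, the annotation, the strand setting and the treatment of reads shared between genes are not given in the sources used here. Reads shared between paralogs, pseudogenes and overlapping genes can therefore raise or lower single counts.

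The table has 19610 gene rows, of which 19417 are annotated as protein coding. Gene coordinates, GC content and the length of the longest protein-coding transcript came from GENCODE release 29 on GRCh38. Symbols matched directly for 19271 rows and through a synonym for 276, and 63 rows had no match. Total counts were 11658728 to 15437602 per library, and counts on nuclear genes 6066305 to 8999358. A count of 0 allows up to 3 counts, or 0.194 to 0.257 CPM, and such limits and the 95% Wilson intervals cover counting error only.

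Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr kept 12196 genes, TMM set the scaling, and glmQLFit with robust estimation and glmQLFTest compared SGC707 with DMSO, with no covariate. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. Standard errors were the log2 fold change divided by the square root of the F statistic. Normalised CPM values use the TMM factors. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, over the 29 lists with at least 5 tested members, and again with an estimated correlation and with fry. Lists of Schwann-like and epithelial markers had fewer than 5 tested members and were not tested.

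The tests, gene lists and most alternatives were fixed before the data were examined. The genes named in the text follow a rule fixed at the same time. It takes PRMT3, IGF1R, MAPT, HTR2C and MIR448, and, where fewer than 10 genes pass the threshold, the 10 with the smallest p that have a mean of at least 5 CPM, groups that do not overlap and a symbol that is not clone-based. It adds 4 members with the smallest adjusted p from each list that passes camera, of which 1 is not reported here. Genes named outside this rule, ELAVL4, GSK3A, EGR1 and MMP2 in the results and others in the closing section, were chosen after their values were seen.

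Alternatives fixed at the same time were RLE size factors, library totals alone, no filter, a stricter filter (1 CPM in 3 libraries and a mean count of 50), DESeq2 1.42.0, limma-voom, each library left out in turn, the replicate letter as a block and a threshold of 0.01. Chosen after seeing the data were a correction for GC content and length, the same correction with each library left out, limma-voom with library weights, a fit without the mitochondrial genes, the estimated correlation with each library left out, and the estimated correlation and fry after the correction. The correction fitted a lowess curve (span 0.3) of each library's deviations on GC content and then on length, over nuclear genes with a mean count of at least 20, and entered edgeR as offsets. Several of these fits call far more genes than the test fixed beforehand, which is the one reported.

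The procedure was tested on simulated data with the real means and library sizes of this comparison of 3 against 3. With the fitted spread, over 12075 genes, edgeR recovered 38.4% of genes changed 2-fold and 98% of those changed 4-fold, with 6 false calls. With the GC trends of the libraries added, over 12112 genes, it recovered 37.4% and 94.9% with 0 false calls, and 68.7% and 99.0% with 8 false calls after the correction. In these simulations genes varied independently, with the spread fitted for their mean count, so genes with a wider spread can be missed more often. In the real data SEMA6D, with a log2 fold change of -2.18, did not pass (edgeR adjusted p = 0.0768). A list shifted 1.5-fold was found by camera (adjusted p = 3.07e-13), by camera with an estimated correlation (adjusted p = 0.0285) and by fry (adjusted p = 0.0111). Genes were drawn independently there and without GC trends, and the shift was larger than the median of any real list but the mitochondrial one. It therefore does not show how these tests fare on lists whose members vary together. Figures were drawn with matplotlib 3.10.9.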

Results

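RNA sequencing measured transcript levels in SH-SY5Y cells, an established human neuroblastoma line with features of adrenergic neurons. One group of 3 libraries came from cells given SGC707, an inhibitor of the protein arginine methyltransferase PRMT3, and the other group of 3 came from cells given the solvent DMSO. Replicates are lettered A, B and C in each group. Dose and duration are not given in the sources used here, and nothing in them says that the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. Total counts were 13119834, 15437602 and 11863696 in DMSO A, B and C, and 11885296, 11658728 and 12127187 in SGC707 A, B and C. Counts on nuclear genes were 6121988, 6066305 and 6327895 in DMSO A, B and C. In SGC707 A, B and C they were higher, at 8999358, 8708162 and 7559322, so depth on nuclear genes differed between the groups. No pair of libraries within a group agreed within sampling noise, with a chi-square of at least 9.53 per degree of freedom, and all 6 were used as separate samples.

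The study asked how the inhibitor acts on the microRNA MIR448, on the growth factor receptor gene IGF1R and on phosphorylation of tau, the microtubule-binding protein encoded by MAPT. None of the measured genes of this question passed the test. IGF1R (GRCh38 chromosome 15, 98648539 to 98964530) stood at 45.6 ± 1.03 normalised CPM with DMSO and 42.0 ± 2.29 with SGC707 (SD, n = 3), a log2 fold change of -0.12 (95% interval -0.44 to 0.20, edgeR adjusted p = 0.756). MAPT (chromosome 17, 45894382 to 46028334) stood at 23.0 ± 6.97 and 16.9 ± 7.48 normalised CPM (SD, n = 3), a log2 fold change of -0.44 (95% interval -1.33 to 0.44, edgeR adjusted p = 0.663). Leaving out 1 library moved the MAPT value to -0.68 without DMSO A, -0.28 without DMSO B, -0.76 without SGC707 A and -0.13 without SGC707 B, and that of IGF1R to -0.08 without SGC707 A. PRMT3 itself (chromosome 11, 20387530 to 20509294) stood at 16.2 ± 1.32 and 20.6 ± 2.32 normalised CPM (SD, n = 3), a log2 fold change of 0.34 (95% interval -0.07 to 0.76, edgeR adjusted p = 0.479).

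Adjusted over the list alone, the smallest edgeR adjusted p of these 3 genes was 0.282, that of PRMT3. An inhibitor of the enzyme need not change PRMT3 mRNA, so this gene does not check the labels. MIR448 lies on chromosome X, 114823454 to 114823564, in an intron of the serotonin receptor gene HTR2C on the same strand, and was not analysed here. HTR2C had 1 count in SGC707 B and 0 in the other 5 libraries, where 0 counts allow up to 0.194 to 0.253 CPM by counting error alone, so no difference was detectable at this depth. With scaling by library totals alone, IGF1R (0.55) and MAPT (0.23) had positive log2 fold changes and PRMT3 (0.99) passed the threshold at an edgeR adjusted p of 0.0451, but that scaling also moved the median of all tested genes to 0.69.

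**Figure D1:**
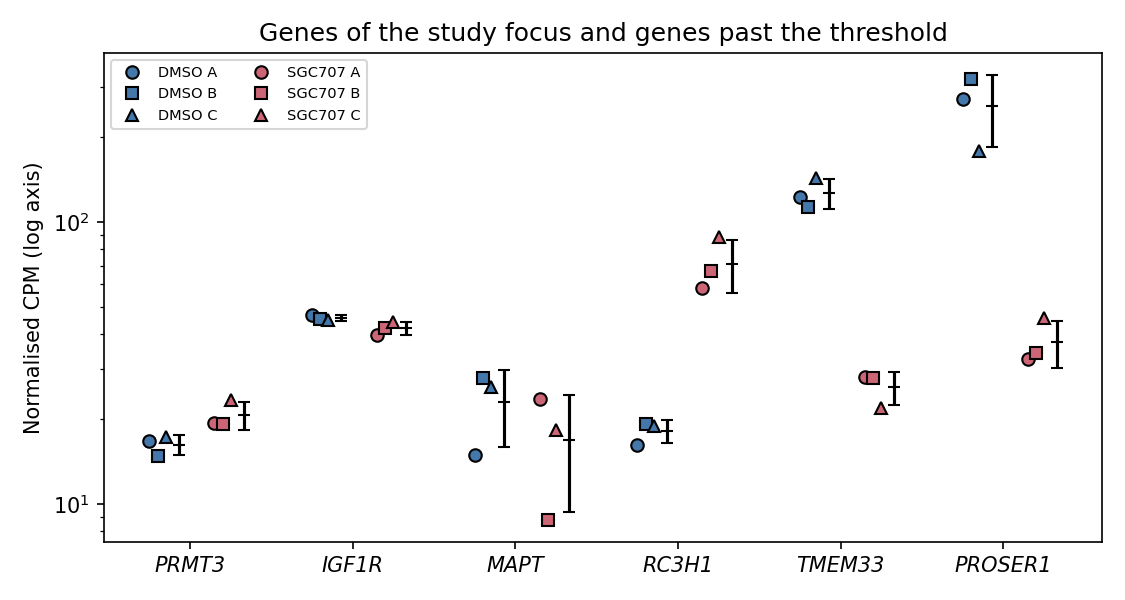
Normalised CPM (log axis) of PRMT3, IGF1R and MAPT and of the 3 genes past the threshold, with 1 point per library and the mean with its SD (n = 3) beside each group. The groups do not overlap for RC3H1, TMEM33 and PROSER1. Those of PRMT3 and IGF1R, which did not pass, do not overlap either, though IGF1R comes close (44.3 in SGC707 C against 44.7 in DMSO C). The MAPT groups overlap, at 23.0 ± 6.97 with DMSO and 16.9 ± 7.48 with SGC707.

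Of 12196 tested genes, 1 rose and 2 fell with SGC707, and all 3 changed at least 2-fold. RC3H1 (chromosome 1, 173931214 to 174022297), which encodes the RNA-binding ubiquitin ligase Roquin-1, rose from 18.1 ± 1.67 to 71.1 ± 15.3 normalised CPM (SD, n = 3), a log2 fold change of 1.97 (SE 0.20, edgeR adjusted p = 0.0431). TMEM33 (chromosome 4, 41935120 to 41960572), which encodes a membrane protein of the endoplasmic reticulum, fell from 126.2 ± 15.5 to 26.0 ± 3.51 normalised CPM (SD, n = 3), a log2 fold change of -2.28 (SE 0.17, edgeR adjusted p = 0.0154). PROSER1 (chromosome 13, 39009866 to 39038076), which encodes a proline- and serine-rich protein, fell from 257.6 ± 73.2 to 37.6 ± 7.13 normalised CPM (SD, n = 3), a log2 fold change of -2.78 (SE 0.26, edgeR adjusted p = 0.0323). Each of the 3 genes had its 3 SGC707 libraries on one side of its 3 DMSO libraries. This was also true of 20.6% of all tested genes, PRMT3 and IGF1R among them, so it adds no separate support.

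The next 7 genes by p-value did not pass the test. The semaphorin gene SEMA6D had a log2 fold change of -2.18 (edgeR adjusted p = 0.0768). RIPOR1 (-1.80), the RNA polymerase II subunit gene POLR2A (-1.67) and the mitochondrially encoded MT-ND6 (1.25) each had an edgeR adjusted p of 0.115. The cyclin gene CCNT2 stood at -1.47 (edgeR adjusted p = 0.131), and the lysosomal genes TPP1 (-1.69) and PLBD2 (-1.96) shared an edgeR adjusted p of 0.137. At an unadjusted p under 0.05 there were 1555 genes, 685 higher and 870 lower, and leaving out 1 library moved this number from 703 (without DMSO B) to 3723 (without SGC707 C), with 769 without DMSO A and 967 without SGC707 B. With scaling by library totals alone, 5949 genes were higher and 54 lower at that level. The 3 SGC707 libraries lay all above or all below the 3 DMSO libraries in 2509 genes, or 20.6% of those tested, where chance gives 10% on average. Genes vary together between libraries, so a single split can exceed 10% without an effect of SGC707. Setting DMSO A, DMSO B and SGC707 C against the rest gave 1500 genes at an unadjusted p under 0.05 in edgeR.

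The number of genes past the threshold depended on single libraries and on the method. No gene passed in edgeR when DMSO A, DMSO B or SGC707 B was left out, 462 rose and 685 fell without SGC707 C, DESeq2 on all libraries gave 47 higher and 239 lower, and scaling by library totals alone gave 2574 higher and 31 lower. SGC707 C stood apart from the other libraries in a trend with GC content: its deviations from the gene means had a Spearman correlation across genes of -0.78 with transcript GC content, against 0.52 and 0.34 in SGC707 A and B and 0.24, 0.18 and -0.14 in DMSO A, B and C. The gene means include SGC707 C, so its trend by itself moves those of the other libraries the opposite way. A correction for GC content and length, chosen after seeing the data, gave 9 higher and 53 lower genes.

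**Figure D2:**
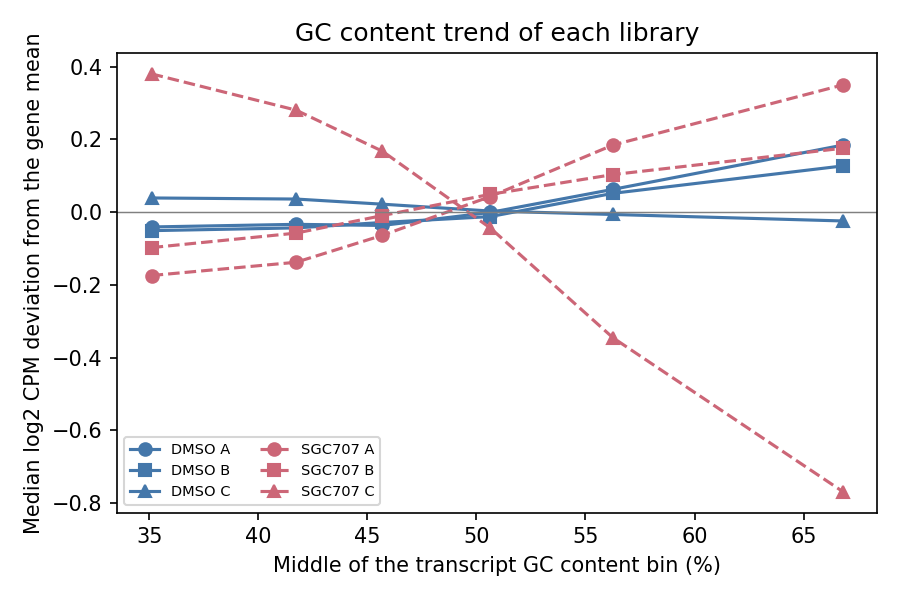
Median deviation of log2 CPM from each gene's mean over the 6 libraries, in 6 bins of transcript GC content with 1758 genes each, with 1 line per library (DMSO solid, SGC707 dashed). SGC707 C runs from 0.38 in the lowest bin to -0.77 in the highest, and SGC707 A from -0.17 to 0.35.

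Mitochondrially encoded transcripts took a smaller share of the counts with SGC707. The share was 53.3%, 60.7% and 46.7% in DMSO A, B and C and 24.3%, 25.3% and 37.7% in SGC707 A, B and C, or 53.6% ± 7.02 against 29.1% ± 7.45 (SD, n = 3, two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). Each library's 95% Wilson interval spans less than 0.1 percentage points and covers counting error only. Of the 13 measured genes of the mitochondrial list, 12 had negative and 1 had positive log2 fold changes, with a median of -1.44, and the list shifted down by camera (adjusted p = 4.69e-09; adjusted p = 0.602 with an estimated correlation). No member passed the gene test over all genes, and 13 passed adjusted over the list alone. MT-CYB (-1.68, edgeR adjusted p = 0.173), which encodes cytochrome b, and the complex I subunit genes MT-ND1 (-1.66, edgeR adjusted p = 0.190) and MT-ND4L (-1.92, edgeR adjusted p = 0.202) were the lower members with the smallest p. MT-ND6, the complex I subunit encoded on the opposite strand to the other 12, had 281, 220 and 316 counts in DMSO A, B and C and 1025, 956 and 776 in SGC707 A, B and C (log2 fold change 1.25, SE 0.16). MT-ND4L overlaps MT-ND4 on the same strand, and the strand setting of the authors' counting is not given in the sources used here, so counts of overlapping and antisense genes are uncertain.

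**Figure D3:**
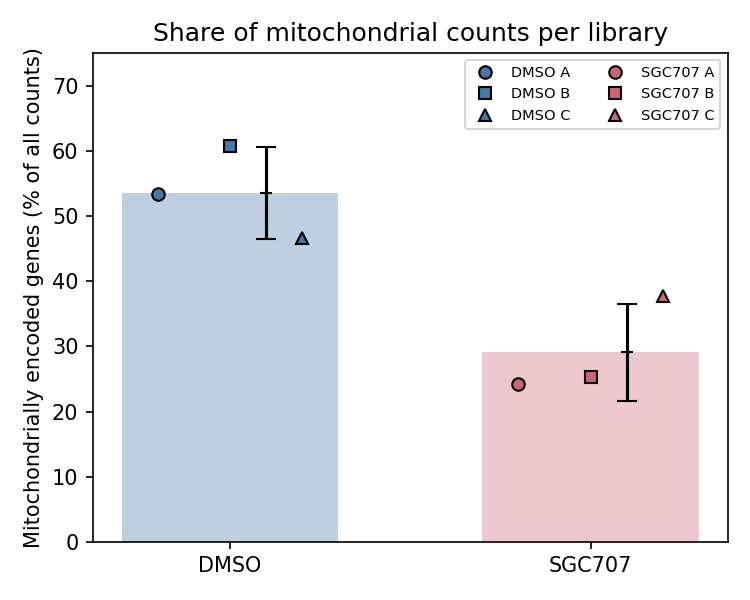
Mitochondrially encoded genes as a percentage of all counts, with 1 point per library, bars at the group mean and error bars of 1 SD (n = 3). The SGC707 libraries lie between 24.3% and 37.7%, all below the DMSO libraries at 46.7% to 60.7%.

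The camera test with its preset correlation found 3 lists shifted up: cytosolic ribosomal proteins, nuclear oxidative phosphorylation, and the ATF4 and amino acid response. No member of these lists passed the gene test. Among 79 cytosolic ribosomal protein genes, 63 had positive log2 fold changes, with a median of 0.27 (camera adjusted p = 5.57e-04; adjusted p = 0.655 with an estimated correlation), and of 0.13 without SGC707 A (camera adjusted p = 0.0460). Its members with the smallest p were RPS14 (0.96), RPL9 (0.74), RPL22 (0.47) and RPL10 (0.94), with edgeR adjusted p from 0.178 to 0.266. Among 38 nuclear genes of oxidative phosphorylation, 31 were positive, with a median of 0.30 (camera adjusted p = 5.64e-04; adjusted p = 0.655 with an estimated correlation). UQCRH (0.69) and NDUFA8 (0.69) had positive log2 fold changes and SDHB (-0.73), a subunit of succinate dehydrogenase, a negative one, with edgeR adjusted p from 0.243 to 0.272. Among 26 genes of the ATF4 and amino acid response, 21 were positive, with a median of 0.24 (camera adjusted p = 0.0159; adjusted p = 0.655 with an estimated correlation). PSAT1 (0.52) and PHGDH (0.59), enzymes of serine synthesis, DDIT4 (0.86), an inhibitor of mTORC1 signalling, and the cystine transporter gene SLC7A11 (0.66) had edgeR adjusted p from 0.291 to 0.377. Adjusted over the list alone, 0 members of each of these 3 lists passed in edgeR, with 17, 8 and 4 members higher and 2, 2 and 0 lower at an unadjusted p under 0.05. After the GC and length correction the camera call of the ribosomal list ended (adjusted p = 0.130), as did that of the nuclear oxidative phosphorylation list (adjusted p = 0.112). Without SGC707 A or SGC707 B the call of the ATF4 list ended (camera adjusted p = 0.122 and 0.181), and its median was 0.38 without SGC707 C. The median of the nuclear oxidative phosphorylation list was 0.17 without SGC707 A (camera adjusted p = 0.0197). Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain.

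The lists of synapse and neurite, tubulin and microtubule, and adrenergic neuroblastoma identity genes shifted down by the same test. Among 34 synapse and neurite genes, 24 had negative log2 fold changes, with a median of -0.32 (camera adjusted p = 5.64e-04; adjusted p = 0.602 with an estimated correlation). The adhesion gene NCAM1 (-1.29), the SNARE genes VAMP2 (-1.18) and SNAP25 (-0.81) and the synaptic vesicle gene SYN1 (-0.88) had edgeR adjusted p from 0.163 to 0.256. Among 21 tubulin and microtubule genes, 18 were negative, with a median of -0.27 (camera adjusted p = 0.00114; adjusted p = 0.602 with an estimated correlation). TUBA1C (-1.06), TUBB4A (-1.97), TUBB2A (-0.61) and TUBG1 (-0.51) had edgeR adjusted p from 0.163 to 0.349, and tubulin genes share reads with close paralogs. Among 28 genes of adrenergic neuroblastoma identity, 19 were negative, with a median of -0.20 (camera adjusted p = 0.0174; adjusted p = 0.602 with an estimated correlation). The transcription factor genes GATA3 (-1.14), HAND1 (-0.82) and TFAP2B (-0.53) and the developmental gene MAB21L1 (-0.44) had edgeR adjusted p from 0.142 to 0.2997. Adjusted over the list alone, 5 synapse genes (the 4 above and ELAVL4), 2 tubulin genes (TUBA1C and TUBB4A) and 2 adrenergic genes (GATA3 and HAND1) passed in edgeR. The tubulin median was -0.17 without DMSO B, and its call held with each library left out (camera adjusted p up to 0.0421). The call of the adrenergic list ended without SGC707 C (camera adjusted p = 0.168) and after the GC and length correction (adjusted p = 0.0556). With library totals alone the 3 medians were positive (0.37, 0.43 and 0.46) and lay below the 0.69 median of all genes, with TUBB2A (0.12), TUBG1 (0.21), TFAP2B (0.15) and MAB21L1 (0.26) turned positive.

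**Figure D4:**
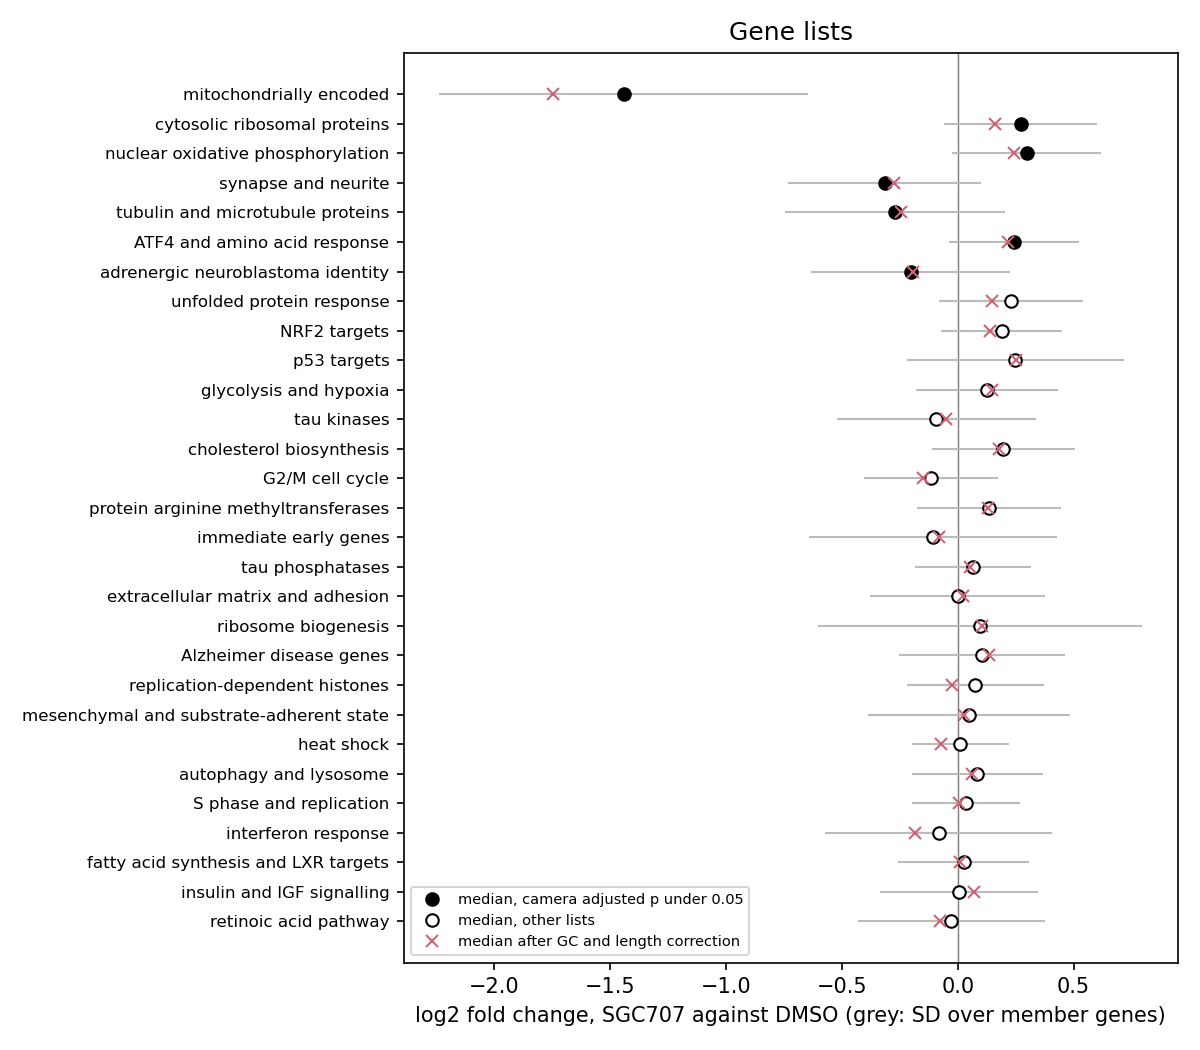
Median log2 fold change, SGC707 against DMSO, of 29 gene lists in order of their camera p-value, with grey lines for 1 SD over member genes. Filled points mark the 7 lists past the threshold with camera's preset correlation, 0 of which pass with an estimated correlation, and crosses give the medians after the GC and length correction.

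The other 22 lists did not pass, with camera adjusted p from 0.0852 to 0.935. With 1 library left out 5 of them passed: G2/M genes (median -0.298, camera adjusted p = 0.00826), p53 targets (0.258, 0.0225) and glycolysis and hypoxia (0.197, 0.0421) without SGC707 C, NRF2 targets (0.159, 0.0371) without DMSO B, and the unfolded protein response (0.276, 0.0429) without DMSO C. With an estimated correlation 0 of the 29 lists passed camera in any of the fits without 1 library (lowest adjusted p = 0.497, 0 or 1 list at an unadjusted p under 0.05). Lists close to the study's question were among them. Tau kinases had 10 positive and 19 negative members (median -0.09, camera adjusted p = 0.241), and 1 member, GSK3A (log2 fold change -1.08), passed in edgeR adjusted over the list alone (adjusted p = 0.0169; 0.163 over all genes). Tau phosphatases had 19 positive and 7 negative members (median 0.07, camera adjusted p = 0.487). Insulin and IGF signalling had 18 positive and 15 negative members (median 0.01, camera adjusted p = 0.935), protein arginine methyltransferases 8 and 3 (median 0.14, camera adjusted p = 0.329) and Alzheimer disease genes 10 and 7 (median 0.10, camera adjusted p = 0.656). Stress lists gave medians of 0.23 for the unfolded protein response, 0.19 for NRF2 targets, 0.25 for p53 targets and 0.01 for heat shock. Proliferation lists gave -0.12 for G2/M genes, 0.04 for S phase and replication, 0.07 for replication-dependent histones and 0.10 for ribosome biogenesis. Metabolic and lysosomal lists gave 0.12 for glycolysis and hypoxia, 0.20 for cholesterol biosynthesis, 0.03 for fatty acid synthesis and LXR targets and 0.08 for autophagy and lysosome. The remaining lists gave -0.11 for immediate early genes, -0.08 for interferon response genes, 0.05 for the mesenchymal and substrate-adherent state, -0.03 for the retinoic acid pathway and -2.59e-04 for extracellular matrix and adhesion. Adjusted over the list alone, the immediate early gene EGR1 (-1.64) and the matrix protease gene MMP2 (-0.86) passed in edgeR; ELAVL4, GSK3A, EGR1 and MMP2 are named because of their values. Over the fits without 1 library the medians of these lists moved: tau kinases from -0.134 to -0.0461 (without SGC707 A), tau phosphatases from 0.0438 to 0.130 (without SGC707 B), Alzheimer disease genes from 0.0620 (without SGC707 A) to 0.115, cholesterol biosynthesis from 0.0127 (without SGC707 A) to 0.206, p53 targets from 0.0675 (without SGC707 A) to 0.275, the unfolded protein response from 0.144 (without DMSO B) to 0.276, and G2/M genes from -0.298 (without SGC707 C) to -0.0356 (without SGC707 B). Glycolysis and hypoxia ranged from 0.0298 (without SGC707 B) to 0.197, autophagy and lysosome from 0.0207 to 0.132, S phase from 0.0162 to 0.0920, histones from 0.0258 to 0.218, and matrix and adhesion from -0.0833 to -7.05e-04. Median and camera direction differed in sign for the heat shock, insulin and IGF, mesenchymal and retinoic acid lists.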

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

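The GC and length correction, the library weights, the fit without mitochondrial genes and the estimated correlation with 1 library left out were chosen after seeing the data. RLE size factors, the stricter filter and the fit without mitochondrial genes gave the 1 higher and 2 lower genes again, all 3 of them the genes called on all libraries. The count of higher genes, lower genes and genes changed at least 2-fold was 2574, 31 and 1182 with library totals only, 1, 5 and 6 with no filter on low counts, 47, 239 and 147 with DESeq2, 0, 2 and 2 with limma-voom (1561 genes at an unadjusted p under 0.05), 9, 53 and 35 after the correction, 1596, 1855 and 448 with library weights, and 0, 0 and 0 at an adjusted p under 0.01. Leaving out 1 library gave 0 to 462 higher, 0 to 685 lower and 0 to 228 changed at least 2-fold, with the highest values without SGC707 C, 0, 0 and 0 without DMSO A, DMSO B or SGC707 B, 0, 5 and 5 without DMSO C, and 5, 4 and 9 without SGC707 A. After the correction, leaving out 1 library gave 1 to 330 higher, 0 to 634 lower and 1 to 253 changed at least 2-fold, and both C libraries raised the count when left out (330, 599 and 253 without DMSO C, 291, 634 and 197 without SGC707 C). The replicate block gave 0, 0 and 0, with 1534 genes at an unadjusted p under 0.05. Whether the letters pair the libraries is not given in the sources used here, and this is not settled by values: deviations from the group means of same-lettered libraries correlated across genes at 0.08, -0.02 and 0.10, and 3 of the 6 libraries correlated best with their own letter. Across the alternatives RC3H1 stayed positive (1.78 to 2.61, adjusted p 1.22e-12 to 0.402), and TMEM33 (-2.36 to -1.61, adjusted p 2.22e-25 to 0.157) and PROSER1 (-2.99 to -2.09, adjusted p 7.37e-21 to 0.184) stayed negative. With library totals only, PRMT3 passed the threshold (0.99), and IGF1R (0.55), MAPT (0.23), TUBB2A (0.12), TUBG1 (0.21), TFAP2B (0.15) and MAB21L1 (0.26) turned positive, none past the threshold; that scaling moved the median of all genes to 0.69. Over all alternatives the adjusted p of PRMT3 ran from 0.0451 to 0.915, that of IGF1R from 0.0870 to 0.947 and that of MAPT from 0.194 to 0.956. The 7 lists were 0 with an estimated correlation (1 list at an unadjusted p under 0.05), 0 with fry (4 at an unadjusted p under 0.05), 4 after the correction, 0 after it with an estimated correlation (0 at an unadjusted p under 0.05) or fry (9), 0 with an estimated correlation and 1 library left out (0 or 1), 7 with the replicate block or RLE, and 6 to 9 with 1 library left out. The direction turned (by camera, or by fry against camera) only in lists that passed under none of these settings: insulin and IGF signalling (median 0.0692) and histones (-0.0265) after the correction, fatty acid synthesis with the block (-0.0083), retinoic acid with fry's own direction (median -0.0274 in both), and, under at least 1 of the fits without 1 library, whose medians ranged as given, fatty acid synthesis (0.00914 to 0.0479), heat shock (-0.121 to 0.0582), immediate early genes (-0.277 to 0.00495), insulin and IGF signalling (-0.0159 to 0.0947), interferon response (-0.1498 to 0.0686), the mesenchymal state (-0.0718 to 0.0392) and retinoic acid (-0.132 to 0.283). Of the values of named genes other than PRMT3, IGF1R and MAPT, 457 kept direction and side of the threshold, 112 were newly past it, 14 no longer past it and 4 turned. For the differences between settings the cause was not tested. In simulation with independent genes, 38.4% of 2-fold changes were recovered at this depth and fitted spread, so changes of this size or smaller can be missed.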

Other observations

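Of the tests below, the splits and the first placement of SGC707 C were planned, and the other placements and the tests of GC content, scaling, mitochondrial yield and gene lists were chosen after the result was seen. The genes of this and the next paragraph were also chosen after their values were seen. Without SGC707 C, 1147 of 12392 tested genes passed in edgeR, and with them more members of the fixed lists. Of 79 ribosomal protein genes 18 rose and 0 fell, among them RPS9 (log2 fold change 1.11, adjusted p = 0.0272) and RPL10 (1.19, adjusted p = 0.0272). Of 30 G2/M genes 7 fell and 0 rose, among them the kinetochore motor gene CENPE (-0.92, adjusted p = 0.0272) and NUSAP1 (-0.83, adjusted p = 0.0309). Of 34 synapse and neurite genes 8 fell and 0 rose, among them SNAP25 (-1.06, adjusted p = 0.0272), the neurofilament gene NEFM (-1.06, adjusted p = 0.0272) and the RNA-binding protein gene ELAVL4 (-1.02, adjusted p = 0.0298). Of 26 genes of the ATF4 and amino acid response 6 rose and 0 fell, among them DDIT4 (1.12, adjusted p = 0.0272) and PHGDH (0.82, adjusted p = 0.0277). Of 33 genes of insulin and IGF signalling 2 rose and 2 fell, near the share of all genes, and the list did not pass (camera adjusted p = 0.944). IGFBP2 (1.02, adjusted p = 0.0272) and AKT1 (0.77, adjusted p = 0.0335) rose and SOS1 (-0.71, adjusted p = 0.0277) and PIK3R2 (-0.47, adjusted p = 0.0354) fell. With all libraries, the adjusted p of each of these genes lies above 0.05, and RPS9, for example, has a log2 fold change of 0.79 (adjusted p = 0.402).

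After the GC and length correction, with all 6 libraries, 62 genes passed, 51 of which also passed without SGC707 C. The tau kinase gene GSK3A fell (log2 fold change -1.08, SE 0.16, adjusted p = 0.0475), as did GATA3 (-1.12, SE 0.16, adjusted p = 0.0475), TUBB4A (-1.95, SE 0.22, adjusted p = 0.0475), the lysosomal protease gene TPP1 (-1.69, SE 0.23, adjusted p = 0.0475) and the homeobox gene SIX3 (-1.55, SE 0.23, adjusted p = 0.0475). The syndecan gene SDC1 (0.98, SE 0.15, adjusted p = 0.0475) and MT-ND6 (0.99, SE 0.13, adjusted p = 0.0475) rose. In the uncorrected fit GSK3A had the same direction (-1.08, adjusted p = 0.163).

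Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 1 higher gene, which 3 splits reached (highest other 1), 2 lower genes, which 1 split reached (highest other 1), 3 genes changed at least 2-fold, which 1 split reached (highest other 2), and 7 lists, which 2 splits reached (highest other 7). The other split with 7 lists set DMSO A, DMSO B and SGC707 C against the rest, with 1500 genes at an unadjusted p under 0.05 against 1555 in the real split.

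SGC707 C stood apart from SGC707 A and B, with a mean root-mean-square log2 difference of 0.777 against 0.472 for the DMSO pair farthest apart. After the GC and length correction the values were 0.527 against 0.463. The GC and length trend is therefore argued against as the whole cause, as far as the correction removed it. A wrong label on a DMSO library stays open: on the genes called from the other 5 libraries C had a median position of 0.0791 (0 is the DMSO mean, 1 that of SGC707 A and B), with 55.3% of genes on the side of A and B, as such a library would give, but 0.517 and 87.6% after the correction. On the 500 leading corrected genes, with each library placed by a fit of the other 5, C lay at 0.488 and DMSO A, B and C at -0.063, -0.228 and 0.516, so C was nearer to SGC707 than DMSO A and B and not nearer than DMSO C. On 300 genes picked from replicates A and B alone, C lay nearer to SGC707 than DMSO C by 0.248 after the correction and in 75.3% of genes (83.0% of the lower and 50.7% of the higher genes), and in 74.9% of the lower and 36.6% of the higher genes without it. Single genes chosen after their values were seen also went both ways: TMEM33 (21.9 CPM in C against 113 to 143 in DMSO), RC3H1 (88.1 against 16.2 to 19.3), PROSER1 (45.7 against 178 to 322), MT-ND6 (60.5 against 21.5 to 28.4) and HAND1 (80.7 against 122 to 160) lay on the side of SGC707 A and B, whereas YIPF6 (log2 0.0117 from the DMSO mean in C, -3.13 in A and B) and ZNF678 (1.28 and -2.37) did not.

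DMSO C was also intermediate, at a median position of 0.540 on those 300 genes after the correction (10th to 90th percentile 0.190 to 0.820), and it had the lowest mitochondrial share of the DMSO libraries. Across 10561 genes, which are not independent replicates, DMSO C minus DMSO B correlated with SGC707 A and B minus DMSO A (Pearson r = 0.328, and 0.357 after the correction), and DMSO C minus DMSO A with SGC707 A and B minus DMSO B (0.242 and 0.275), each a pair of differences that share no library, and DMSO A minus DMSO B correlated at 0.0991 with SGC707 A and B minus DMSO C.

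The lower level of mitochondrially encoded transcripts with SGC707 held under each scaling. The median log2 fold change of the 12 genes other than MT-ND6 was -0.887 under library totals, the scaling with the smallest fall. That value restates the smaller share of the counts, which no scaling between libraries changes, and is no separate test. After the GC and length correction the median was -1.78. The curves were fitted on nuclear genes, so this argues only against the trend seen in nuclear genes as the cause of the fall. It does not show whether mitochondrial RNA follows the same curves. MT-ND6, with a log2 fold change of 1.25 (SE 0.16), went against a lower yield of all mitochondrial RNA. It is a single gene on the opposite strand with 220 to 1025 counts per library. Antisense counts are uncertain without the strand setting, so MT-ND6 does not settle that question. Taken relative to the mean of the other 12 genes in each library, the group differences of these 12 had an SD of 0.257, against a root mean square SE of 0.132 and an SD of 0.268 in another split of the libraries (0.255, 0.124 and 0.252 after the correction), so a lower yield of the 12 alike and a change in the cells cannot be told apart. On that relative scale 5 of the 12 genes had groups that did not overlap, where chance gives 10% and 20.6% of all tested genes did so in CPM. The SD was more than 2 times the median SE of 0.111. The 12 values are dependent, as each is relative to their own mean and some of these genes overlap on the same strand. Neither value therefore decides on an equal loss of all 12. The mitochondrial share differed between the groups without overlap, at a permutation p that 3 against 3 cannot bring below 0.1.

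For 3 of the 6 other lists past camera's threshold, the GC trend is argued against as the whole cause, as far as the correction removed it. Synapse and neurite genes had a median log2 fold change of -0.32 (SD 0.42) before and -0.28 (SD 0.42) after the correction (camera adjusted p = 0.00594 after it). Tubulin and microtubule genes had -0.27 and -0.25 (camera adjusted p = 0.00594). The ATF4 and amino acid response had 0.24 and 0.22 (camera adjusted p = 0.00337). The correction used the longest protein-coding transcript of each gene, which need not be the one expressed, so some trend may remain. For ribosomal protein genes the median went from 0.27 (SD 0.33) to 0.16 (SD 0.34) and the call ended at an adjusted p of 0.130, for nuclear oxidative phosphorylation from 0.30 (SD 0.32) to 0.24 (SD 0.34) at 0.112, and for adrenergic identity from -0.20 (SD 0.43) to -0.19 (SD 0.43) at 0.0556. For these 3 the median kept more than 0.5 of its value while the call was lost. The trend, an effect of SGC707 and differences between single libraries therefore cannot be told apart. The adrenergic median hardly moved under the correction, and its call also ended without SGC707 C (camera adjusted p = 0.168). With an estimated correlation or fry 0 of the lists passed, before or after the correction (after it, lowest adjusted p = 0.650 and 0.0689, with 0 and 9 lists at an unadjusted p under 0.05), so an effect of SGC707 on any of them stays a hypothesis.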
